A study of Mus musculus with 22 samples.

How the data were processed

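Livers of 22 mice were profiled on Affymetrix arrays, 1 array per animal. Per the labels' protocols and the series' design text, colonies of the mutant lines were kept, double-heterozygous mice on a mixed C57BL/6 and 129/Sv background were intercrossed to give Trim24-/-, Trim24-/- Rara+/- and wild-type (WT) offspring, livers were frozen, total RNA was column-purified, and biotin-labelled probes were hybridised. Groups came from the labels alone: 4 WT, 4 Trim24-/- and 4 Trim24-/- Rara+/- animals at 5 weeks, and 5 WT and 5 Trim24-/- animals at 14 weeks. Animals are named by the number in their label, those at 14 weeks by the end of their title.

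The authors deposited intensity values on a linear scale for 45101 probe sets and 22 arrays. Signal ran from 0.0191 to 17200.2, and the mean after trimming 2% of values from each end was 100.001 on every array, so the values had been scaled to a common level before deposit. The software and its settings are not given in the sources used here. No arrays were identical. The median signal was 14.2 over the arrays at 5 weeks and 22.8 at 14 weeks. Between 49.9% and 54.4% of probe sets read below the pseudocount of 16 on the arrays at 5 weeks, and 37.8% to 45.3% on those at 14 weeks. Among 8334 genes above a log2 level of 6, correlations between arrays of a group ran from 0.948 to 0.992.

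Gene symbols came from a platform annotation that lists 35890 probe sets, of which 34958 have 1 symbol and 932 several, and 9211 probe sets are not listed there. Probe sets with several symbols or none named no gene. For each of 18194 genes the probe set with the highest mean over all 22 arrays was used, a choice that matters for the 9012 genes with several. By Entrez number, 18032 genes matched a RefSeq table of GRCm38.p6, and 0 symbols needed updating. The genome build behind the array annotation is not given in the sources used here, so that table served only for which genes neighbour each other, and no coordinates are reported.

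Values were tested as log2(signal + 16) with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. The 3 comparisons at 5 weeks came from 1 fit of 12 arrays, the comparison at 14 weeks from a fit of 10 arrays, and the interaction of genotype and age and the comparison of WT ages from a fit of all 22. No covariates were used. The named genes were set by a rule: Trim24, Rara and the sex-chromosome list always, the 10 largest rises and 10 largest falls per comparison among called genes whose groups do not overlap (no such condition for the interaction), and up to 4 called members of each fixed list with the smallest adjusted p. These rules, the lists, the tests with limma, camera and fry and the alternatives, other than those named here as added or chosen later, were fixed before the data were examined. Some tests of explanations were chosen after the results were seen, and they are named beside those results.

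Gene lists, 35 in number with 620 members of which 544 were measured, covered interferon responses, antigen presentation, retinoid biology, metabolism, stress, sex-biased liver genes, zonation, and markers of other cell types. Each was tested with limma's camera at a preset correlation of 0.01 between genes, with the correlation estimated from the arrays, and with fry, and p was adjusted over the 35 lists of a comparison. Camera compares a list with all other genes, whereas fry does not. An exact permutation test of list means per array was added after the estimated correlations were seen. Overlaps were tested with Fisher's exact test. The shared WT arrays were addressed by simulating unchanged groups and by splitting the WT arrays. The return of called genes toward WT was also computed on 10 simulated datasets with no return, a step added after the results were seen.

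The fits were tested on simulated data with 200 changed genes among the 18194, in 10 datasets per comparison. At 2-fold, 85.6% of changed genes were found in the comparison of Trim24-/- with WT at 5 weeks, 87.0% for Trim24-/- Rara+/- with WT, 85.0% for Trim24-/- Rara+/- with Trim24-/-, 89.8% at 14 weeks, 60.6% for the interaction and 88.8% for WT ages. At 1.5-fold these shares were 34.2%, 34.4%, 33.2%, 37.8%, 10.6% and 41.4%. False calls made up between 4.61% and 5.56% of calls. The simulated genes were independent and had the same spread in every group. Real arrays need not meet these conditions, so the shares may not hold for them.

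Alternatives were quantile normalisation, centring each array, only genes of above-median brightness, pseudocounts of 1 and 64, the mean of all probe sets or every probe set, a variance trend, array weights, a 2-fold minimum, genes near the targeted alleles left out, other sets of arrays in the fit, and each array left out in turn. Chosen after the arrays were seen were leaving out WT animal 90 and Trim24-/- animal 6, averaging Trim24-/- Rara+/- animals 54, 66 and 82, which resemble each other, and averaging Trim24-/- animals 1 and 8, which do so too. A covariate for sex was not used, since the arrays of each age showed 1 pattern of sex-linked genes. P-values of limma, fry and the exact permutation tests measure the spread between the sampled animals. Those of camera and Fisher's exact test, and shares of random gene sets, take genes as their units and do not measure that spread directly.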

Results

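Liver gene expression was measured on 22 one-colour oligonucleotide arrays, each hybridised with RNA from the liver of 1 mouse. Trim24 is a transcriptional co-regulator of the tripartite motif family, and Rara encodes retinoic acid receptor alpha, a nuclear receptor that switches genes in response to retinoic acid. At 5 weeks of age there were 4 wild-type (WT), 4 Trim24-/- and 4 Trim24-/- Rara+/- animals, the last carrying 1 intact Rara allele. At 14 weeks there were 5 WT and 5 Trim24-/- animals. The series asks how loss of Trim24 affects interferon signalling in the liver and whether that effect passes through Rara. The probe sets of each array gave 18194 named genes. Signals were linear, with the same trimmed mean of 100.001 on each array, and were tested as log2(signal + 16), so that fold changes of dim genes are understated. The median signal per array lay between 12.6 and 16.1 at 5 weeks and between 19.7 and 25.9 at 14 weeks. The number of arrays limits the precision.

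The targeted genes were examined first. Trim24 signal at 5 weeks was 317 ± 111 (SD, n = 4) in WT, 363 ± 84.7 in Trim24-/- and 450.4 ± 34.1 in Trim24-/- Rara+/- livers. At 14 weeks it was 168 ± 24.2 (SD, n = 5) in WT and 235 ± 59.3 in Trim24-/- livers. The difference between Trim24-/- and WT was 0.23 ± 0.22 (SE) on the log2 scale at 5 weeks (limma, adjusted p = 0.766) and 0.43 ± 0.16 at 14 weeks (adjusted p = 0.457). Rara was dim, at 12.3 ± 11.7 in WT, 13.7 ± 8.45 in Trim24-/- and 18.2 ± 9.97 in Trim24-/- Rara+/- livers at 5 weeks. The part of each gene that the probes cover relative to the disrupted part is not given in the sources used here, and probes outside the disrupted part check nothing, so neither gene tests the genotype labels.

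The sexes are not given in the labels. Xist, the RNA that silences 1 X chromosome in females, read between 948 and 2169 on all 12 arrays at 5 weeks and between 13.4 and 44.5 on all 10 arrays at 14 weeks. The Y-linked Eif2s3y showed the opposite, at 0.350 to 6.59 at 5 weeks and 245 to 344 at 14 weeks. Each comparison between genotypes at 1 age was therefore made among animals with the same pattern of sex-linked signals, and comparisons between ages were not.

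Loss of Trim24 at 5 weeks was accompanied by higher expression of interferon-response genes and lower expression of several genes of fatty acid oxidation. Oas1a, whose product makes the 2'-5' oligoadenylates that activate RNase L, rose from 93.8 ± 16.5 to 473 ± 219 (SD, n = 4 in each group), and Ifi27l2a rose from 94.2 ± 25.8 to 337 ± 62.3. Gbp6, a guanylate-binding protein of cell-autonomous immunity, rose 4.97-fold, from 112 ± 21.1 to 664 ± 318. Cfap53, a gene of motile cilia, read 488 ± 342 against 4.77 ± 1.34 in WT, a level below the pseudocount, so that no fold is given. Mbd1, which binds methylated CpG sites, rose 9.02-fold (from 323 ± 71.1 to 3012 ± 404). In the other direction, Cyp4a14, a fatty acid omega-hydroxylase, fell from 5356 ± 366 to 3061 ± 531, and Acot1, an acyl-CoA thioesterase, from 742 ± 206 to 239 ± 112.

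In all, 109 genes passed an adjusted p of 0.05 in limma, 86 higher and 23 lower in Trim24-/- than in WT, of which 52 and 6 changed at least 2-fold. The log2 changes were 3.17 ± 0.22 (SE) for Mbd1 (adjusted p = 6.73e-05), 2.83 ± 0.25 for the complement component C6 (adjusted p = 2.75e-04) and 2.31 ± 0.18 for the oxysterol hydroxylase Cyp7b1 (adjusted p = 1.23e-04). Obp2a, an odorant-binding protein, read 1674 ± 2414 against 9.15 ± 3.10 in WT (5.06 ± 0.71, adjusted p = 0.0109). For genes below the pseudocount in WT it sets the size: with pseudocounts of 64 and 1 the log2 change was 3.64, no longer called, and 6.38 for Obp2a, and 2.82 and 6.19 for Cfap53. The largest fall was that of the hydroxysteroid sulfotransferase Sult2a2, at -2.75 ± 0.43 (adjusted p = 0.0191), followed by the ion channel gene Asic5 at -2.00 ± 0.35, while ornithine aminotransferase, Oat, fell by 1.23 on the same scale (adjusted p = 0.0194). The groups did not overlap for 1004 of 18194 genes, where chance alone gives 2.86% of genes. Such genes numbered 840 between Trim24-/- Rara+/- and WT and 1540 between Trim24-/- Rara+/- and Trim24-/-, with the same chance share. The count of 109 depended on single arrays: it was 12 without WT animal 45, 14 without Trim24-/- animal 8, 29 without Trim24-/- animal 1, 39 without WT animal 44, and 60, 64 and 68 without Trim24-/- Rara+/- animals 54, 66 and 82. It was 34 with a pseudocount of 1, 19 when only the 8 arrays of the compared groups were fitted and, by choices made after the arrays were seen, 28 with animals 54, 66 and 82 averaged as 1 replicate and 21 with Trim24-/- animals 1 and 8 averaged, whereas C6, Cfap53, Cyp2u1, Cyp7b1, Gbp6, Ifi27l2a, Mbd1 and Psmb9 passed under all 27 alternatives.

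Of 46 measured interferon-stimulated genes, 15 rose at 5 weeks and none fell. All but 1 had a positive estimate, and 40 passed when p was adjusted over the list alone. The nucleic acid sensor Zbp1 (2.31 ± 0.36, SE) and Oas3 (0.96 ± 0.15, or 0.38 and 1.96 with pseudocounts of 64 and 1, its WT level lying below the pseudocount) were among them. The list had a median log2 change of 1.11 (camera with a preset correlation, adjusted p = 5.57e-44). Its call was lost when the correlation between genes was taken from the arrays (adjusted p = 0.110 with an estimated correlation). Fry, which tests whether a list moves on balance 1 way, gave 0.0107. Interferon-inducible GTPases rose in 7 of 9 members, 9 adjusted over the list alone, with Igtp, which acts on pathogen vacuoles, going from 763 ± 175 to 2079 ± 596. Their median was 1.45 (adjusted p = 2.84e-18, and adjusted p = 0.0611 with an estimated correlation). In the list of MHC class I antigen presentation and immunoproteasome genes, 3 of 13 rose and 8 did when adjusted over the list alone: the proteasome subunits Psmb9 (1.39 ± 0.17) and Psmb8 (1.01 ± 0.19) and the peptide transporter Tap1 (1.41 ± 0.23), for which 2 of 3 other probe sets went the other way. Its median was 0.57 (adjusted p = 6.84e-12, and adjusted p = 0.110 with an estimated correlation). An exact permutation test of the mean of each list per array gave 0.0286 for these 3 lists, the smallest p that 4 against 4 arrays allow, and 0.2 after adjustment. No list could pass that adjustment unless most of the 35 reached the smallest p, so it decides nothing at 5 weeks.

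Among 21 genes of fatty acid oxidation and PPARa targets, 3 fell at 5 weeks: Acot1, Cyp4a14 and Ehhadh, a peroxisomal beta-oxidation enzyme that went from 3221 ± 598 to 1882 ± 254. Their calls were lost under 9, 7 and 18 of 27 alternatives. Adjusted over the list alone 7 genes fell, and 20 of the 21 estimates were negative, with a median of -0.22 (camera, adjusted p = 2.99e-08, and adjusted p = 0.110 with an estimated correlation). Macrophage and Kupffer cell markers had positive estimates in 19 of 20 members and a median of 0.39, but only Mpeg1, a pore-forming protein of macrophages, passed among all genes, at 991 ± 263 against 293 ± 63.8, and 7 adjusted over the list alone. That list's adjusted p was 8.17e-07, and adjusted p = 0.406 with an estimated correlation, and its median was 0.22 without Trim24-/- animal 37 and 0.60 without WT animal 90. Its mean per array on the log2 scale was 7.52 ± 0.28 (SD, n = 4) in WT and 8.01 ± 0.38 in Trim24-/- livers. The arrays of these groups overlapped, at 7.25 to 7.91 and 7.69 to 8.50. The interferon-stimulated list had means of 6.94 ± 0.15 and 8.13 ± 0.54, and its median rose to 1.28 without Trim24-/- animal 37. In Trim24-/- Rara+/- livers the means were 7.74 ± 0.25 for macrophage markers and 6.96 ± 0.24 for the interferon-stimulated list. Of the lists for targets of p53, stellate cell and matrix markers and T and NK cell markers, no member passed among all genes in limma, while 4, 5 and 5 members had an unadjusted p under 0.05. Adjusted over the list alone, 1, 0 and 2 did. Their medians were 0.41, 0.43 and 0.18 (camera, adjusted p = 0.00101, 0.00134 and 0.00995, and adjusted p = 0.333, 0.495 and 0.406 with an estimated correlation). The p53 median was 0.20 without WT animal 2, and its call was lost without Trim24-/- animal 6 (0.24, adjusted p = 0.0633). Without Trim24-/- animal 37 the calls of stellate cell markers (0.23, adjusted p = 0.0692) and of T and NK cell markers (0.21, adjusted p = 0.0610) were lost, and the latter's median was 0.31 without Trim24-/- animal 1 and 0.29 without WT animal 90. Over the brighter genes alone the median of T and NK cell markers was -0.32. None of 21 retinoic acid targets passed in limma (median -0.02), 2 had an unadjusted p under 0.05 and 1 passed adjusted over the list alone.

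Genes that differ between male and female liver moved both ways at 5 weeks. In the male-biased list, C6, Cyp7b1 and Cyp2d9, a steroid-hydroxylating cytochrome, rose out of 13 members. Adjusted over the list alone, 3 passed higher and 1 lower, and the list's median of -0.01 differed in sign from its mean of 0.56 and its test (upward, adjusted p = 0.0485, and adjusted p = 0.495 with an estimated correlation). The median was 0.22 without WT animal 2 and 0.12 without Trim24-/- animal 6 or 37, and the call was lost without any one of WT animals 44 and 90, Trim24-/- animals 1, 6 and 8 and the 4 Trim24-/- Rara+/- animals (adjusted p = 0.0565 to 0.145). In the female-biased list Sult2a2 and Cyp4a14 fell out of 18 members, 1 passed higher and 3 lower adjusted over the list alone, and the median was -0.21 (adjusted p = 0.0485, and adjusted p = 0.333 with an estimated correlation). That median was -0.02 without WT animal 2 and -0.04 without WT animal 44, and the call was lost without any one of WT animals 44 and 90, Trim24-/- animals 1, 6 and 8 and Trim24-/- Rara+/- animals 66 and 73 (adjusted p = 0.0526 to 0.211). Oat was the only pericentral hepatocyte marker to fall among 12 (2 adjusted over the list alone), with a list median of -0.15 (adjusted p = 0.00971, and adjusted p = 0.495 with an estimated correlation). The pericentral median was -0.30 without WT animal 90, and its call was lost without WT animal 44, at -0.02, or Trim24-/- animal 6, at -0.06.

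**Figure D1:**
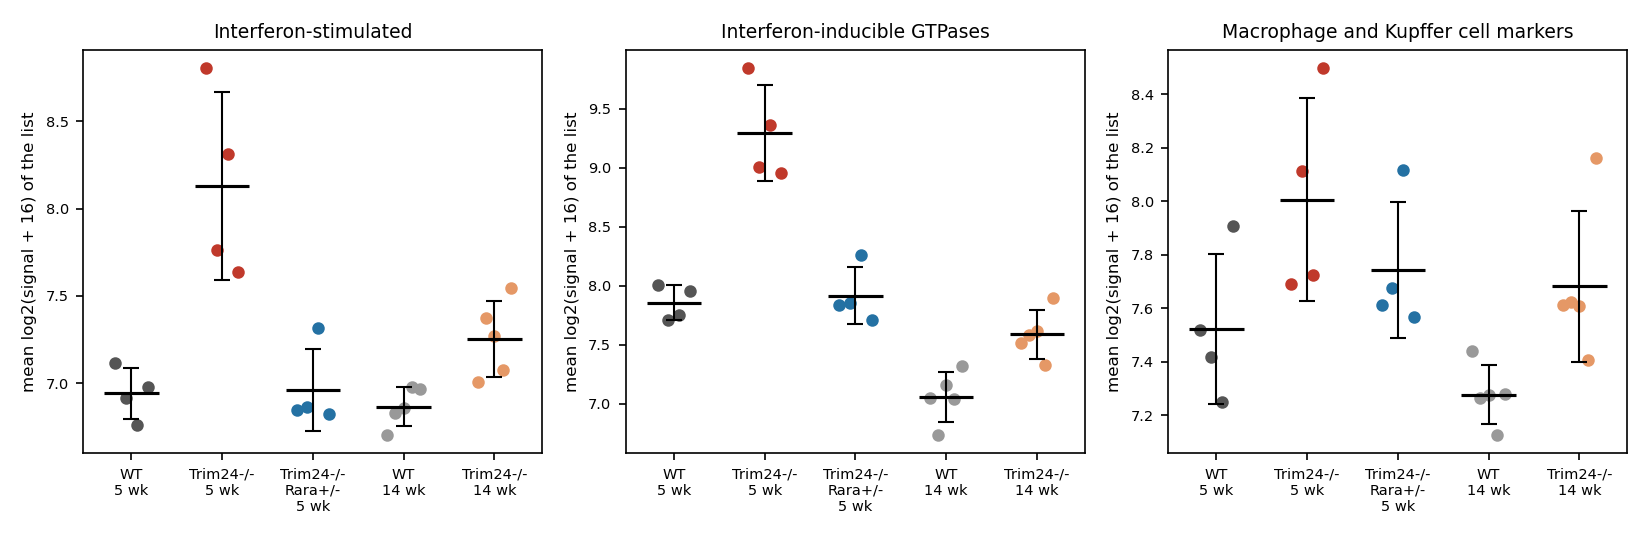
Mean log2(signal + 16) of the interferon-stimulated, interferon-inducible GTPase and macrophage lists on each array, by group. Points are arrays, thick bars group means and thin bars 1 SD; for the interferon-stimulated list the 4 Trim24-/- arrays at 5 weeks lie between 7.64 and 8.80, above the 4 WT arrays at 6.76 to 7.12.

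Trim24-/- livers with 1 Rara allele were next set against WT, which asks what remains changed when a Rara allele is removed. A lower Rara level was not seen on the arrays, where the gene was dim. The series has no Rara+/- animals with intact Trim24. A reversal of the Trim24-/- changes therefore cannot be told apart from a separate effect of losing a Rara allele. Interferon-response genes did not stand out: of the interferon-stimulated list, none of 46 passed in limma, among all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. The list's median was 0.05 (camera, adjusted p = 0.412, and adjusted p = 0.852 with an estimated correlation), its sign turning to -0.05 without Trim24-/- Rara+/- animal 73 and to -0.02 without WT animal 45. What stayed higher was a small set led by Cfap53 (685 ± 406 against 4.77 ± 1.34, SD, n = 4), Obp2a, Mbd1 (4931 ± 1458 against 323 ± 71.1), C6 (739 ± 71.9 against 104 ± 64.4) and Cyp7b1 (2364 ± 265 against 456 ± 33.3). Zfp445, a zinc finger protein that maintains imprints, read 1378 ± 75.3 against 518 ± 41.6.

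This comparison called 10 genes, 9 higher and 1 lower, with log2 changes of 4.91 ± 0.43 (SE) for Cfap53 (limma, adjusted p = 2.63e-04, and 3.30 or 6.75 with a pseudocount of 64 or 1), 3.83 ± 0.22 for Mbd1 (adjusted p = 6.91e-06) and -0.60 ± 0.09 for Acyp1, an acylphosphatase (adjusted p = 0.0480). The GTPases had no call in limma and no member with an unadjusted p under 0.05 (median 0.06, or -0.01 without animal 73). Of the 21 genes of fatty acid oxidation and PPARa targets none was called either, and 2 had an unadjusted p under 0.05 (median 0.06, mean -0.05). By camera, 5 lists were called: male-biased liver (2 of 13 higher, 4 higher and 1 lower adjusted over the list alone, median 0.32), endothelial markers (0.16), cell cycle (0.22), macrophage markers (0.15) and stellate cell markers (0.22), each with adjusted p = 0.805 with an estimated correlation. In the last 4 no member passed in limma, adjusted over the list alone or not, and 0, 2, 2 and 1 had an unadjusted p under 0.05. Neither fry nor an estimated correlation called any list here. The male-biased median was -0.10, 0.74 and 0.16 without WT animals 44, 2 and 90 and 0.18 without Trim24-/- Rara+/- animal 82. The macrophage call was lost without WT animal 2 (0.14), 44 (0.12) or 45 (0.04) or Trim24-/- Rara+/- animal 73 (-0.03), and its median was 0.30 without WT animal 90. The cell cycle call was lost without WT animal 2 (0.11) or 90 (0.01) or Trim24-/- Rara+/- animal 54 (0.17) or 82 (0.15), its median being 0.40 without WT animal 45 and -0.02 over the brighter genes. The endothelial call was lost without WT animal 45 (0.12), and that of stellate cell markers without any one of WT animals 44, 45 and 90 and Trim24-/- Rara+/- animals 54 and 73 (adjusted p = 0.0517 to 0.219). For Cyp7b1, 1 of 2 other probe sets went the other way. Under 27 alternatives the call was lost in 20 for Acyp1, 14 for Cyp2u1, 13 for Obp2a, 12 for Bmyc and 1 for Cyp4v3. C6, Cfap53, Cyp7b1, Mbd1 and Zfp445 kept theirs. Calls were 6 without any one of WT animal 45, Trim24-/- animal 8 and Trim24-/- Rara+/- animals 54 and 66, and 22 and 21 without Trim24-/- animals 6 and 37. Other fits gave 31 when all 22 arrays were fitted together and, by choices made after the arrays were seen, 28 without both WT animal 90 and Trim24-/- animal 6, 5 with Trim24-/- Rara+/- animals 54, 66 and 82 averaged and 6 with Trim24-/- animals 1 and 8 averaged.

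All 9 genes called higher against WT in Trim24-/- Rara+/- were also called higher in Trim24-/-, where independent lists would share 0.0425, and the 1 lower gene, Acyp1, was shared too. Both comparisons use the same WT arrays. Their log2 changes correlated across genes with r = 0.469, and unchanged groups simulated against the same WT arrays gave 0.502. The covariance was 0.0285 against 0.0163 simulated, a difference of 0.0122. The simulation gave every group the same spread, whereas the covariance from shared arrays depends on the spread of the WT arrays. The difference therefore does not by itself show a shared effect. With the WT arrays split between the comparisons, r lay between -0.10 and 0.24 over 6 splits.

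**Figure D2:**
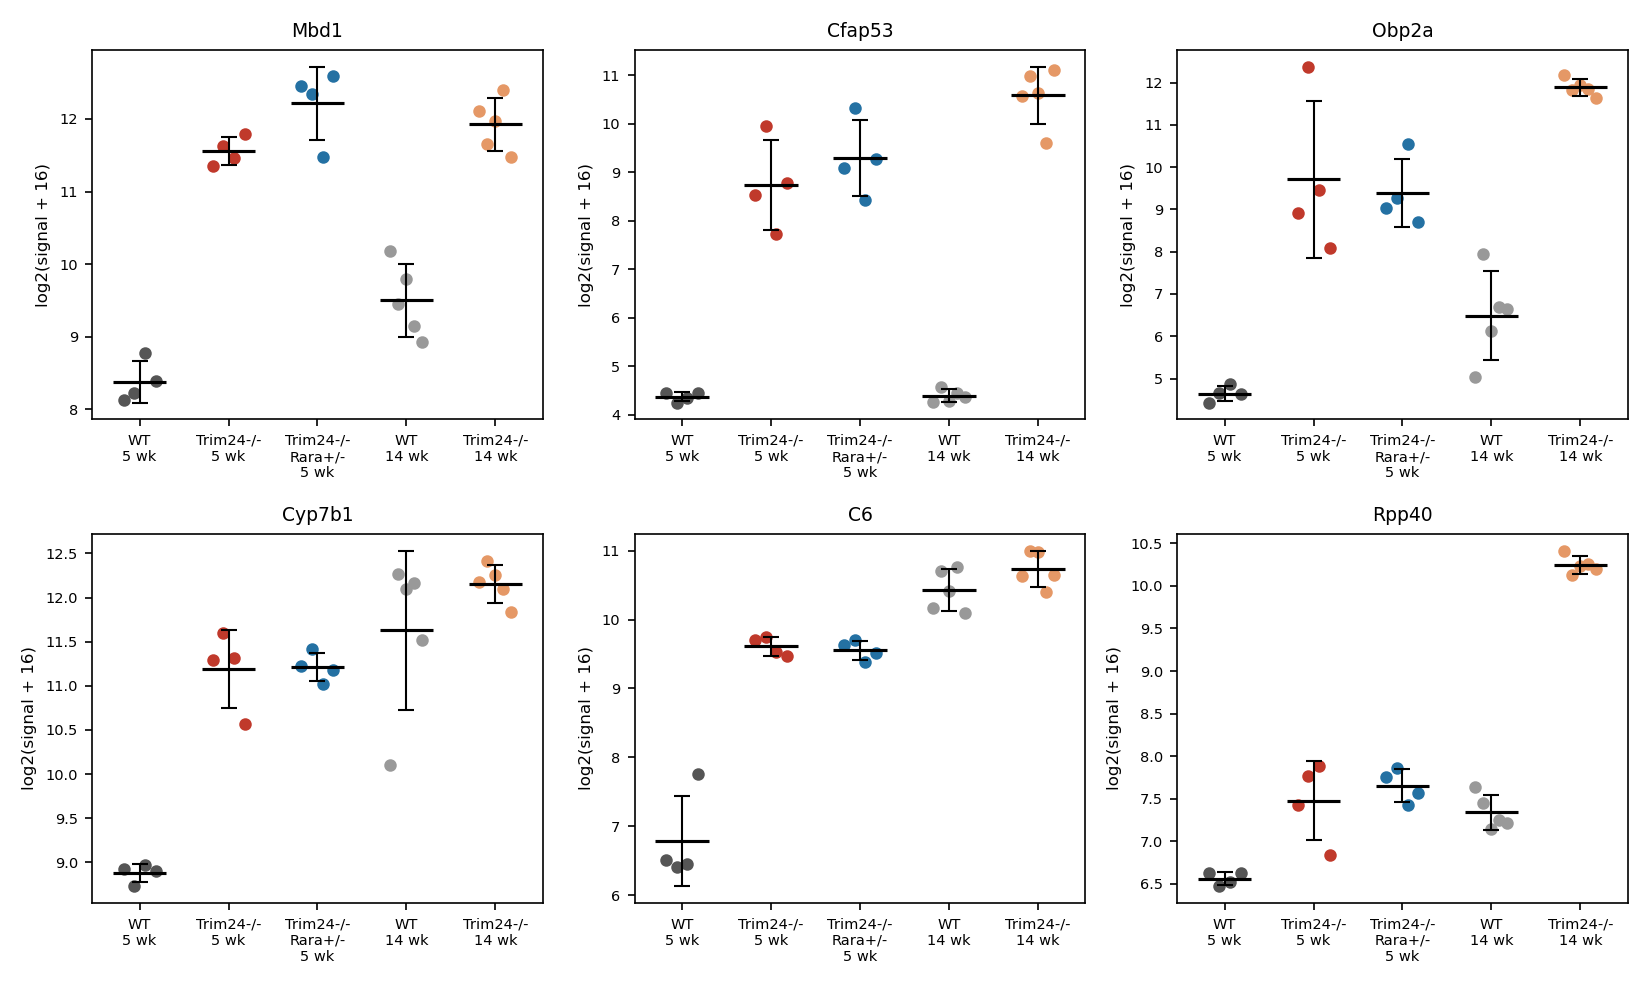
log2(signal + 16) of Mbd1, Cfap53, Obp2a, Cyp7b1, C6 and Rpp40 on each array, by group. Points are arrays, thick bars group means and thin bars 1 SD; Cfap53 lies at the floor on the WT arrays (group means of 4.77 and 5.06 in signal) and at 488, 685 and 1614 in the mutant groups.

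Direct comparison of Trim24-/- Rara+/- with Trim24-/- livers at 5 weeks asks which changes the removal of 1 Rara allele alters. Interferon-response genes were lower with the Rara allele removed. Gbp6 fell from 664 ± 318 to 133 ± 37.02 (SD, n = 4), Igtp from 2079 ± 596 to 595 ± 25.9, Ifi27l2a from 337 ± 62.3 to 115 ± 40.0, and Rtp4, an interferon-induced chaperone of receptor transport, from 1419.6 ± 439.8 to 341 ± 185. Genes of fatty acid metabolism rose: Acot1 from 239 ± 112 to 860.2 ± 146 and Cyp4a14 from 3061 ± 531 to 5939 ± 356. Noct, a circadian-regulated phosphatase gene, rose from 394 ± 94.8 to 853 ± 38.8, and the linker histone gene H1f2 fell from 647 ± 88.3 to 238 ± 30.0.

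There were 26 calls, 7 higher and 19 lower, with 4 and 13 changed at least 2-fold. Log2 changes were -2.11 ± 0.27 (SE) for Gbp6 (limma, adjusted p = 0.0226), -1.73 ± 0.21 for Igtp (adjusted p = 0.0193), 1.88 ± 0.29 for Acot1 (adjusted p = 0.0275) and 0.97 ± 0.13 for Cyp4a14 (adjusted p = 0.0226). In the interferon-stimulated list 4 of 46 fell, 39 adjusted over the list alone, with a median of -1.05 (camera, adjusted p = 2.44e-39, and adjusted p = 0.141 with an estimated correlation). In the GTPases 4 of 9 fell, 8 adjusted over the list alone, with a median of -1.43 (adjusted p = 4.87e-16, and adjusted p = 0.0927 with an estimated correlation). In the MHC class I list 1 of 13 fell, Tap1, and 5 adjusted over the list alone, with a median of -0.46 (adjusted p = 5.03e-08, and adjusted p = 0.222 with an estimated correlation). In the fatty acid oxidation list 2 of 21 rose, 4 adjusted over the list alone, with a median of 0.26 (adjusted p = 5.03e-08, and adjusted p = 0.141 with an estimated correlation). Fry called these 4 lists, with the largest adjusted p at 0.0359. Endothelial markers were positive in all 14 members, of which none passed in limma, 1 passed adjusted over the list alone and 5 had an unadjusted p under 0.05 (median 0.30, adjusted p = 6.91e-06, and adjusted p = 0.255 with an estimated correlation). Macrophage markers had a median of -0.20 (adjusted p = 0.0141, and adjusted p = 0.646 with an estimated correlation), with no member called in limma, 1 lower adjusted over the list alone and 5 with an unadjusted p under 0.05. That call was lost without Trim24-/- animal 6 (-0.20) or 37 (-0.03) or Trim24-/- Rara+/- animal 54 (-0.19) or 82 (-0.10), and the median was -0.37 and -0.33 without Trim24-/- animals 1 and 8 and -0.32 without Trim24-/- Rara+/- animal 73.

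The number of calls in this comparison was unstable. It was 0 without Trim24-/- animal 8 or any one of Trim24-/- Rara+/- animals 54, 66 and 82, 5 without Trim24-/- animal 1, 16 without WT animal 45, and 44, 50 and 101 without Trim24-/- animal 6, Trim24-/- Rara+/- animal 73 and Trim24-/- animal 37. A pseudocount of 1 gave 0, averaging animals 54, 66 and 82 gave 0, averaging Trim24-/- animals 1 and 8 gave 5, only the compared groups 5, and array weights 325, while the median of the interferon-stimulated list stayed between -1.28 and -0.93 whichever array was left out.

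Over the 109 genes called between Trim24-/- and WT at 5 weeks, the Trim24-/- Rara+/- mean was shifted toward WT for 101, or 92.7%, and lay closer to WT than to Trim24-/- for 69. Selection and comparison share the Trim24-/- arrays here. In 10 simulated datasets with no return, a step added after the results were seen, 69.5% to 71.7% of the called genes were still shifted toward WT, though the simulated genes were independent and a mean of 1016 were called. When 2 of these arrays selected the genes and the other 2 served for comparison, the share shifted toward WT was 50% to 77.8% over 6 splits, with 10 to 169 genes selected. Over the pooled splits of the simulated datasets the share was 46.4% to 51.6%. A range of pooled shares does not give the spread of single splits, so the comparison does not decide whether the real shares exceed no return. In the 6 splits of the real arrays the median difference of the held-out Trim24-/- arrays from Trim24-/- Rara+/-, in the direction of the call, was -0.04 to 0.66 on the log2 scale, and that from WT, whose arrays also served for selection, 0.67 to 2.59. Measured on the arrays that selected the genes, the share of the change undone was 91.1% for Gbp6, 86.4% for Ifi27l2a, 114% for Acot1 and 118% for Cyp4a14, against 2.07% for C6, -0.776% for Cyp7b1 and -20.8% for Mbd1.

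**Figure D3:**
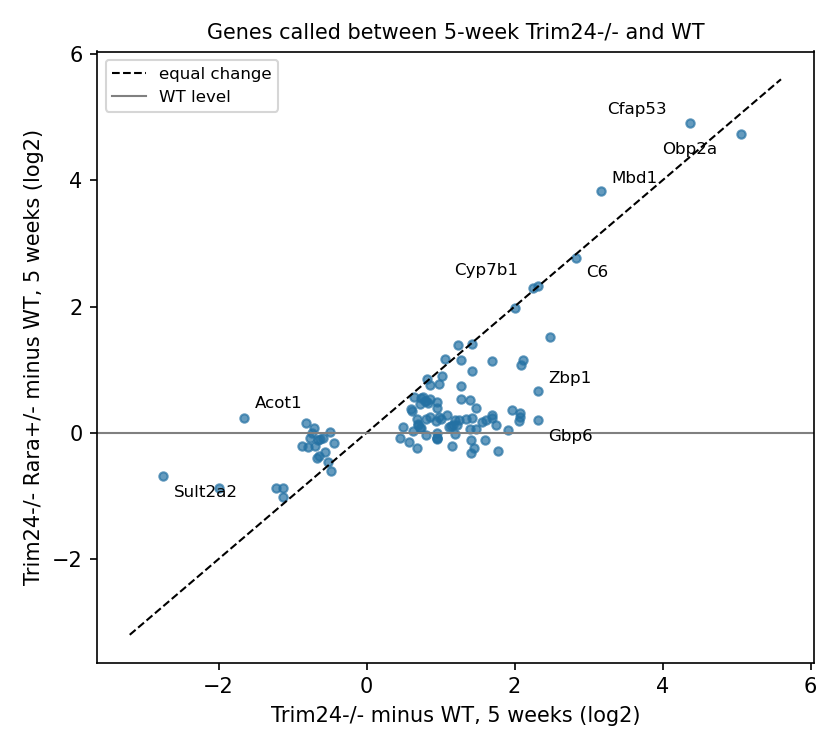
Log2 difference from WT at 5 weeks of the 109 genes called between Trim24-/- and WT, in Trim24-/- (horizontal) and in Trim24-/- Rara+/- (vertical). Each point is a gene; the dashed line marks an equal change and the grey line the WT level. Mbd1, Cfap53, C6 and Cyp7b1 lie near the dashed line, and Gbp6 and Acot1 near the WT level.

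At 14 weeks, loss of Trim24 was again marked by Cfap53, which read 1614 ± 556 against 5.06 ± 2.00 in WT (SD, n = 5), Obp2a, at 3790.4 ± 529.8 against 94.0 ± 80.4, and Mbd1, at 3977 ± 1013 against 745 ± 271. Rpp40, a subunit of ribonuclease P, rose 7.48-fold, from 147 ± 23.6 to 1199.5 ± 92.3, and Resf1, a factor that silences endogenous retroviruses, rose from 120.3 ± 13.7 to 727 ± 142. The p53 targets Ccng1 and Phlda3 rose to 610.04 ± 92.4 and 149 ± 59.9, from 274 ± 31.2 and 36.8 ± 6.74. Of the 46 measured members of the interferon-stimulated list only Usp18, which removes ISG15 from proteins, passed, at 243 ± 72.9 against 96.6 ± 19.3. Oat fell from 3354 ± 180 to 1659 ± 201, and Abcc3, an efflux transporter of conjugated bile acids, from 1273 ± 72.6 to 587 ± 218.

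Of 44 genes called, 33 were higher and 11 lower, with 26 and 5 changed at least 2-fold. Log2 changes were 6.19 ± 0.24 (SE) for Cfap53 and 2.90 ± 0.12 for Rpp40 (limma, adjusted p = 1.14e-07 for each, the former being 4.52 or 8.03 with a pseudocount of 64 or 1), 2.43 ± 0.14 for Resf1 (adjusted p = 6.5e-06), 1.11 ± 0.13 for Ccng1 (adjusted p = 0.00237), -1.02 ± 0.11 for Oat (adjusted p = 0.00152) and -1.16 ± 0.20 for Abcc3 (adjusted p = 0.0352). The groups did not overlap for 324 of 18194 genes, where chance alone gives 0.794% of genes. Without WT animal liver_611WT or Trim24-/- animal liver_466M there were 28 calls, as with a pseudocount of 1. Fitting all 22 arrays together gave 94, and the brighter genes alone gave 74. The call of Usp18 was lost under 14 of 21 alternatives, that of the GTPase gene Gbp8 under 11 of 21 and that of Abcc3 under 11 of 20. Cfap53, Rpp40, Resf1, Ccng1 and Oat kept theirs.

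All 46 interferon-stimulated genes had a positive estimate at 14 weeks, with a median of 0.32. Usp18 was called among all genes and 13 were adjusted over the list alone (camera, adjusted p = 7.59e-18, and adjusted p = 0.260 with an estimated correlation). Of the 9 GTPases, Gbp8 was called and 8 were adjusted over the list alone, with a median of 0.53 (adjusted p = 2.95e-09, and adjusted p = 0.260 with an estimated correlation). The p53 list had a median of 0.31, with 2 of 13 called and 6 higher and 1 lower adjusted over the list alone (adjusted p = 4.75e-05, and adjusted p = 0.260 with an estimated correlation). Macrophage markers were positive in all 20 members, none called in limma, 5 adjusted over the list alone and 11 with an unadjusted p under 0.05 (median 0.39, adjusted p = 1.24e-10, and adjusted p = 0.260 with an estimated correlation). Their mean per array moved from 7.28 ± 0.11 to 7.68 ± 0.28 (SD, n = 5) while that of the interferon-stimulated list moved from 6.87 ± 0.11 to 7.25 ± 0.22. MHC class II genes had a median of 0.58, with none of 6 called in limma, 4 adjusted over the list alone and 4 with an unadjusted p under 0.05 (adjusted p = 0.00187, and adjusted p = 0.432 with an estimated correlation). Gluconeogenesis genes had a median of -0.36, with none of 7 called in limma, 3 lower adjusted over the list alone and 4 with an unadjusted p under 0.05 (adjusted p = 7.74e-04, and adjusted p = 0.416 with an estimated correlation). Fry called 4 lists, the interferon-stimulated, GTPase, p53 and pericentral ones, each at 0.0414.

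The ages shared more Trim24-/- calls than independent lists would. Of the genes called higher, 15 were shared where 0.156 would be by chance (Fisher's exact test, two-sided, p = 3.51e-27): Bmyc, Cfap53, Cyp2u1, Cyp4v3, Gabra3, Gstp3, Ifi27, Mbd1, Obp2a, Phlda2, Resf1, Sertad4, Usp18, Zfp979 and Zfp991. Mn1 and Oat were called lower at both ages, against 0.0139 by chance (Fisher's exact test, p = 8.35e-05), and no gene was called in opposite directions. The sign at 14 weeks was the same for 97 of the 109 genes called at 5 weeks. Across all genes, which are not independent replicates, Spearman's rho of the changes was 0.19 and Pearson's r 0.30.

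Whether the effect of Trim24 loss differed between ages was tested as an interaction over all 22 arrays, and 6 genes passed. The pattern of sex-linked signals and the set of arrays changed with age, so the interaction cannot be credited to age alone. Of the genes that passed, C6 is in the male-biased list and Sult2a2 in the female-biased list. C6 was raised at 5 weeks but read 1706 ± 303 against 1385 ± 295 (SD, n = 5) at 14 weeks, a difference of effects of -2.52 ± 0.31 (SE; limma, adjusted p = 4.00e-04). Rpp40 (1.99 ± 0.23), Slc35f2 (1.88 ± 0.28, or 0.96 and 3.06 with pseudocounts of 64 and 1, the latter no longer called), the mitochondrial complex I assembly gene Dmac1 (1.58 ± 0.24) and Cdpf1 (1.12 ± 0.17) had the larger effect at 14 weeks, and the only other probe set of Slc35f2 went the other way. The sixth, Sult2a2 (3.01 ± 0.49), was near the floor in both genotypes at 14 weeks, at 10.9 ± 6.22 and 6.39 ± 4.88. Calls rose to 11 without Trim24-/- animal 6 of the 5-week group, and to 10 without Trim24-/- animal 37 of that group or WT animal liver_611WT. The interferon-stimulated list had a lower effect at 14 weeks, with a median difference of -0.72, no member called in limma, 23 adjusted over the list alone and 25 with an unadjusted p under 0.05 (camera, adjusted p = 9.42e-25, and adjusted p = 0.143 with an estimated correlation; fry, 0.102). The MHC class I list, at -0.45, kept its call (adjusted p = 3.6e-13, and adjusted p = 0.0404 with an estimated correlation), with 6 of 13 members lower adjusted over the list alone, none called in limma among all genes and 8 with an unadjusted p under 0.05. The GTPases were at -0.89, with no member called in limma, 5 of 9 lower adjusted over the list alone and 5 with an unadjusted p under 0.05 (adjusted p = 8.54e-10, and adjusted p = 0.0725 with an estimated correlation; fry, 0.0276).

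Because loci near a disrupted allele can differ in strain origin, calls were counted around the targeted genes, with gene order from the GRCm38.p6 annotation. Within 20 Mb of Trim24, 4 of 279 genes were called at 5 weeks, Gstk1, Herc6, Parp12 and Zc3hav1l, against 104 elsewhere (Fisher's exact test, two-sided, p = 0.0868). Within 5 Mb there were 3 of 82 (Fisher's exact test, p = 0.0131), and with a 2-fold minimum only Parp12 (Fisher's exact test, p = 0.233). Herc6 and Parp12 are members of the interferon-stimulated list. At 14 weeks 0 of 279 genes were called within 20 Mb of Trim24, as in both comparisons of Trim24-/- Rara+/- livers. Within 20 Mb of Rara, 4 of 628 genes were called between Trim24-/- and WT at 5 weeks (Fisher's exact test, p = 0.791): Ccl2, Lgals3bp, Slfn2 and Slfn4. Within 10 Mb of Rara 0 of 361 were called. In both comparisons of Trim24-/- Rara+/- livers 0 of 628 were called within 20 Mb of Rara. Of the genes named in this paragraph, those not in a fixed list were named after their values were seen.

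WT livers at 14 and 5 weeks differed in 5147 genes, 3576 higher and 1571 lower at 14 weeks. Age, the pattern of sex-linked signals and the set of arrays changed together, so they cannot be told apart. The direction followed sex-biased genes: in the male-biased list 11 of 13 rose, 12 adjusted over the list alone, with a median of 2.38 (camera, adjusted p = 5.75e-09, and adjusted p = 0.114 with an estimated correlation). Of the female-biased list 14 of 18 fell, 14 adjusted over the list alone, with a median of -2.43 (adjusted p = 6.3e-15, and adjusted p = 3.66e-04 with an estimated correlation). Cyp4a12a, an arachidonic acid hydroxylase of male liver, rose from 89.6 ± 105 to 2865 ± 934 (SD, n = 4 and 5), and Hao2, a peroxisomal hydroxyacid oxidase, fell from 1330 ± 431 to 7.03 ± 7.20. The GTPases fell in 7 of 9 members, 8 adjusted over the list alone, with a median of -0.75 (adjusted p = 1.77e-06, and adjusted p = 0.133 with an estimated correlation). In the comparison 14-week WT vs 5-week WT the median gene moved by 0.13 on the log2 scale, and the split of higher against lower calls reversed to 935 against 4901 when each array was centred on its median and became 1843 against 1802 after quantile normalisation.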

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

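The tests of macrophage markers, of a single outlying animal, of sequence flanking the Trim24 allele, of neighbouring genes and of degraded RNA were chosen only after the result was seen, as were leaving out WT animal 90 and Trim24-/- animal 6 and averaging Trim24-/- Rara+/- animals 54, 66 and 82 or Trim24-/- animals 1 and 8.

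Other divisions of the same arrays into groups of the same sizes were tried for each count. For genes, the real division gave the largest count in each comparison except the difference between ages. Between Trim24-/- and WT at 5 weeks it called 109, the highest of the other 34 being 3, for Trim24-/- Rara+/- and WT 10 against 1, for Trim24-/- Rara+/- and Trim24-/- 26 against 9, at 14 weeks 44 against 2 among 100 divisions, and for WT ages 5147 against 2966. Each was reached by 1 division, the real one, which excludes chance as their source only as far as the arrays are exchangeable. A shared litter or day is not given in the sources used here. Trim24-/- Rara+/- animals 54, 66 and 82 correlated with each other at 0.987 to 0.992, and with these averaged as 1 replicate limma called 28, 5 and 0 genes in place of 109, 10 and 26. Trim24-/- animals 1 and 8 correlated at 0.988, and with these averaged the counts were 21, 6 and 5. For the difference between ages, the fitted age effect was removed and age labels were shuffled within each genotype. There 2 of 100 divisions gave as many as the real 6, the highest other also giving 6. That test needs arrays of both ages to be exchangeable. These arrays differed in sex-linked pattern and in probe sets below the pseudocount (49.9% to 54.4% against 37.8% to 45.3%), so the test does not exclude chance. For lists past camera with the preset correlation chance was not excluded: 13 of 35 divisions gave as many as the real 11 between Trim24-/- and WT at 5 weeks (highest other 19), 17 as many as 5 for Trim24-/- Rara+/- and WT (highest other 12), 6 as many as 14 for Trim24-/- Rara+/- and Trim24-/- (highest other 17), and 14 of 100 as many as 11 at 14 weeks (highest other 17).

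The first pattern weighed is the rise of interferon-stimulated genes in Trim24-/- livers at 5 weeks. It was not the work of 1 animal, since 4 of 4 Trim24-/- arrays had a list mean above every WT array, nor of the arrays that stand apart, since the list's median was 1.25 without WT animal 90 and Trim24-/- animal 6. More macrophages may contribute: the 15 markers above a signal of 64 rose by a mean of 0.442 against 1.19 for the list, and the difference of 0.744 did not pass an exact permutation test (two-sided, p = 0.229), so this explanation cannot be told apart from the rest. An effect of Trim24 loss within hepatocytes stays open and was not tested, as does a difference between colonies, since the labels mention colonies of both mutant lines as well as the intercross.

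The second pattern is the set of 15 genes called higher in Trim24-/- livers at both ages. Sequence flanking the Trim24 allele is argued against, since 0 of them lie within 20 Mb of Trim24. For background alleles that segregate freely in the intercross the test decides nothing: 20% of the 60 values of the Trim24-/- Rara+/- arrays lay on the WT side of the midpoint, Phlda2 holding 4 of these 12 values, Ifi27 and Usp18 3 each, Gstp3 and Sertad4 1 each and the other 10 genes 0, but losing a Rara allele can itself bring a gene nearer WT, so such values do not show segregation. Neighbours were more frequent than in random sets, with 3 pairs within 1 Mb (Bmyc and Obp2a, Cfap53 and Mbd1, Zfp979 and Zfp991) against a mean of 0.167 and a share of 0.0013 of 10000 random sets with as many. That is consistent with changes that reach over neighbouring genes, but linked strain alleles that differ between the animals of the groups could give the same pairs and was not tested.

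The third pattern is that WT animal 90 and Trim24-/- animal 6 resemble each other at 5 weeks. Exchanged labels are argued against: over the 33 genes called higher at 14 weeks, 0 of the 2 arrays lay on the side of the other genotype, animal 90 at 6.28 and animal 6 at 7.94 on the log2 scale. Degraded RNA stays open: the higher Actb 3' to 5' log2 ratio of the 2 was 0.763, below the 0.827 to 1.16 of the other 10 arrays, but the Gapdh ratio of animal 90, -0.328, was the highest of the 12, while that of animal 6, -0.457, lay within the -0.479 to -0.350 of the others. No biological explanation was tested.

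Single arrays stood apart in 36 of 390 groups of values, by the gap of the highest or lowest array to its neighbour relative to the range of the group. Chance alone picks out about 1 in 20 groups, or 19.5 here. Trim24-/- Rara+/- animal 73 accounts for 13. Its list means on the log2 scale were 7.31 for interferon-stimulated genes (6.82 to 6.87 in the rest of its group), 10.31 for bile acid genes, 10.67 for fatty acid oxidation, 10.07 for lipogenesis, 10.38 for acute phase genes, 7.22 for the male-biased list and 5.45 for neutrophil markers. Its signals were 188 for Gbp6, 174 for Ifi27l2a, 224 for Oas1a, 634 for Igtp, 615.9 for Rtp4 and 355 for Irgm2, each the highest of its group.

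Among the other arrays at 5 weeks, Trim24-/- animal 6 had a cholesterol synthesis mean of 7.17 (8.88 to 9.10 in the rest of its group) and signals of 5285 for Obp2a, 375 for Bmyc and 143 for Asic5. Trim24-/- animal 37 had list means of 7.01 for male-biased genes and 5.47 for erythroid markers and signals of 104 for Cyp2u1 and 31.7 for Mn1. WT animal 90 had means of 9.34 for endoplasmic reticulum stress and 7.27 for the circadian clock, and a C6 signal of 201. Trim24 read 399.8 in Trim24-/- Rara+/- animal 82, 1700067K01Rik 1.42 in Trim24-/- animal 1, and Eif2s3y 6.58 in WT animal 2.

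At 14 weeks, Trim24-/- animal liver_395M had means of 10.18 for bile acid genes and 8.16 for macrophage markers and a Slc35f2 signal of 124. Trim24-/- animal liver_411M had a stellate cell mean of 6.68 and a Gbp8 signal of 28.6, and Trim24-/- animal liver_463M a female-biased mean of 5.75. WT animal liver_616WT had a xenobiotic metabolism mean of 10.14, and WT animal liver_393WT an endothelial mean of 7.37 and a Uty signal of 42.0.

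Differences between ages cannot be told apart from those between the patterns of sex-linked signals or the sets of arrays. The effect of Trim24 loss differed between ages, as 14 minus 5 weeks on the log2 scale, for C6 (-2.52), Cdpf1 (1.12), Dmac1 (1.58), Rpp40 (1.99), Slc35f2 (1.88) and Sult2a2 (3.01). By camera with the preset correlation it also differed for the interferon-stimulated list (-0.72), interferon-inducible GTPases (-0.89), MHC class I genes (-0.45), the male-biased list (-0.34) and endothelial markers (0.22), of which the MHC class I list alone passed with an estimated correlation. The male-biased value was -0.55 and -0.14 without 5-week WT animals 2 and 44, and the endothelial call was lost without 5-week WT animal 44 (0.21), 5-week Trim24-/- animal 8 (0.15) or WT animal liver_393WT (0.11). Probe sets without a single gene symbol, 10143 in number, held 13 calls between Trim24-/- and WT at 5 weeks, 1 between Trim24-/- Rara+/- and WT, 13 between Trim24-/- Rara+/- and Trim24-/-, and 3 at 14 weeks.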

How the results depend on the processing

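Leaving out WT animal 90 and Trim24-/- animal 6, averaging Trim24-/- Rara+/- animals 54, 66 and 82 or Trim24-/- animals 1 and 8, and the exact permutation of list means were chosen after the results were seen. No paired analysis was possible because the groups share no replicate numbers, and a covariate for sex was not run because each age showed 1 pattern of sex-linked genes. Probe sets below the pseudocount limit what dim genes can show. Apart from the values below, with no array left out, 1290 results for named genes, 174 for lists and 76 counts stayed on their side of the threshold or within 1.5 times, and 249 and 140 for genes and lists lost their call. The cause was not tested for any value below, except that fewer genes or arrays enter some fits by construction.

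Counts of called genes moved by over 1.5 times as follows. Between Trim24-/- and WT at 5 weeks the 109 became 34 with a pseudocount of 1, 58 with a 2-fold minimum, 19 with only the compared groups fitted, 28 with the 3 resembling animals averaged and 21 with animals 1 and 8 averaged. Between Trim24-/- Rara+/- and WT the 10 became 19 with centred arrays or the brighter genes, 18 with array weights, 31 with all 22 arrays in 1 fit, 23 with only the compared groups, 28 without animals 90 and 6, 5 with the 3 animals averaged and 6 with animals 1 and 8 averaged. Between Trim24-/- Rara+/- and Trim24-/- the 26 became 17 with quantile normalisation, all probe sets or a 2-fold minimum, 13 with centred arrays, 102 with the brighter genes, 0 with a pseudocount of 1, 55 with a pseudocount of 64, 52 with a variance trend, 325 with array weights, 101 with all 22 arrays, 5 with only the compared groups, 51 without animals 90 and 6, 0 with the 3 animals averaged and 5 with animals 1 and 8 averaged. At 14 weeks the 44 became 74 with the brighter genes, 28 with a pseudocount of 1 and 94 with all 22 arrays. For 14-week WT vs 5-week WT the 5147 became 3045 with the brighter genes and 598 with a 2-fold minimum. The difference between ages kept its count within 1.5 times under every alternative with no single array left out.

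Centring the arrays changed the split of higher and lower calls from 86 and 23 to 98 and 10 (5-week Trim24-/- vs WT), from 7 and 19 to 5 and 8 (5-week Trim24-/- Rara+/- vs Trim24-/-) and from 33 and 11 to 39 and 6 (14-week Trim24-/- vs WT).

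With an estimated correlation 0 lists were called in the 3 comparisons at 5 weeks and in that at 14 weeks, and the interferon-stimulated list lost its call at medians of 1.11 and -1.05 at 5 weeks (Trim24-/- against WT, Trim24-/- Rara+/- against Trim24-/-) and 0.32 at 14 weeks. The exact permutation of list means also called 0, but at 5 weeks its smallest p, 0.0286, passes adjustment only if most lists reach it, so there it says nothing. At 14 weeks the smallest is 0.00794, and the interferon-stimulated list had an adjusted p of 0.0694. In the difference between ages 1 list was called with an estimated correlation and 2 by fry, and the interferon-stimulated list, at -0.72, lost its call under both. Fry called 4, 0, 4 and 4 lists. For Trim24-/- Rara+/- and WT the 5 lists became 1 with quantile normalisation and 8 without animals 90 and 6, and for Trim24-/- Rara+/- and Trim24-/- the 14 became 9 with the brighter genes and 9 without those animals. Within 5 Mb of Trim24 the 3 called genes passed Fisher's exact test, which those within 10 Mb or 20 Mb did not.

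Ranges in this paragraph are over arrays left out in turn. Directions reversed for Rara, 5-week Trim24-/- vs WT (-0.104 without animals 90 and 6, -0.0591 without WT animal 2 and -0.0542 without WT animal 90, in a range up to 0.351) and between Trim24-/- Rara+/- and Trim24-/- (-0.0269 without Trim24-/- animal 37, in a range up to 0.361, and 0.655 with a pseudocount of 1), and for Trim24 in the difference between ages (-0.0518 with the mean of probe sets). The median of the male-biased liver list, 5-week Trim24-/- vs WT, became 0.0372 with quantile normalisation, 0.528 with the brighter genes, 0.223 without WT animal 2, and 0.119 and 0.124 without Trim24-/- animals 6 and 37, with -0.0416 as the lowest of that range. Between Trim24-/- Rara+/- and WT it ranged from -0.100 without WT animal 44 to 0.745. With the brighter genes, the T and NK cell markers list, 5-week Trim24-/- vs WT, became -0.325, the T and NK cell markers list, 5-week Trim24-/- Rara+/- vs Trim24-/-, became 0.0350, and cell cycle -0.0218 between Trim24-/- Rara+/- and WT. In that comparison, without Trim24-/- Rara+/- animal 73, medians became -0.0535 for interferon-stimulated genes, -0.00968 for GTPases (highest 0.124) and -0.0327 for macrophage markers (highest 0.301), and the interferon-stimulated list, 5-week Trim24-/- Rara+/- vs WT, became -0.0235 without WT animal 45. Cholesterol synthesis between Trim24-/- Rara+/- and Trim24-/- became -0.0106 without Trim24-/- animal 6, or without animals 90 and 6, in a range up to 0.613.

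Leaving out each array in turn gave 12 to 137 calls between Trim24-/- and WT at 5 weeks, 6 to 22 between Trim24-/- Rara+/- and WT, 0 to 101 between Trim24-/- Rara+/- and Trim24-/-, 28 to 39 at 14 weeks, 5 to 11 for the difference between ages and 4281 to 5216 between WT ages. The arrays that decide these counts are named beside each result. Lists called ranged over 8 to 13, 2 to 6, 7 to 18, 9 to 13 and 4 to 8 for the first 5: 2 without WT animal 45, 3 without WT animal 44 or Trim24-/- Rara+/- animal 54, 7 without Trim24-/- animal 6 and 9 without animal 54, and 8 in the difference between ages without Trim24-/- animal 1 or liver_463M. The interferon-stimulated median ranged over 0.94 to 1.28, -0.05 to 0.10, -1.28 to -0.93, 0.29 to 0.38 and -0.91 to -0.57.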

Other observations

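No tests in this part were chosen after the result was seen; its lists were fixed beforehand.

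Further lists passed camera with the preset correlation and not with an estimated one. Between Trim24-/- Rara+/- and Trim24-/- at 5 weeks, gluconeogenesis genes had a median log2 change of 0.30, cholesterol synthesis 0.36, the circadian clock 0.19, cell cycle 0.17, erythroid markers 0.21, pericentral markers 0.20, T and NK cell markers -0.22 and the female-biased list 0.16 (adjusted p = 0.255, 0.668, 0.392, 0.668, 0.2503, 0.646, 0.489 and 0.141 with an estimated correlation). Of these, only the female-biased list had a member called in limma, Cyp4a14. Adjusted over the list alone, 3, 0, 3, 0, 2, 0, 0 and 2 members were higher and 1, of the circadian clock, lower. At an unadjusted p under 0.05 there were 3, 0, 4, 3, 2, 2, 5 and 4. Leaving out Trim24-/- animal 6 ended the calls of cholesterol synthesis (-0.01), the circadian clock (0.20), cell cycle (0.01), erythroid (0.16), pericentral (0.10) and T and NK cell markers (-0.22) and gave 0.04 for the female-biased list. Leaving out Trim24-/- animal 37 ended those of erythroid (0.21), pericentral (0.19) and T and NK cell markers (-0.18) and gave 0.61 for cholesterol synthesis and 0.39 for the female-biased list. Without Trim24-/- animal 1, gluconeogenesis was at 0.20 and cell cycle at 0.25. Calls also ended without Trim24-/- Rara+/- animal 54 for cell cycle (0.14), erythroid (0.25), pericentral (0.18) and T and NK cell markers (-0.14), without animal 66 for cell cycle (0.12) and pericentral markers (0.18), without animal 73 for cholesterol synthesis (0.32), gluconeogenesis (0.33), the circadian clock (0.13) and pericentral markers (0.19), without animal 82 for cell cycle (0.15) and T and NK cell markers (-0.23), and without WT animal 45 for pericentral markers (adjusted p = 0.0509).

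Of lists that passed camera with the preset correlation alone at 14 weeks between Trim24-/- and WT, the fatty acid oxidation list had a median of -0.14, fetal liver genes 0.25, the female-biased list 0.19, hepatocyte markers -0.13 and pericentral markers -0.13 (adjusted p = 0.678, 0.260, 0.481, 0.815 and 0.260 with an estimated correlation). Pericentral markers passed fry too, at 0.0414, and held the only call in limma, Oat. Adjusted over the list alone 0, 2, 0, 0 and 3 members passed, and 3, 3, 4, 2 and 4 had an unadjusted p under 0.05. The fatty acid oxidation call was lost without liver_463M (-0.0072), liver_393WT (-0.0085), liver_616WT (-0.11) or liver_466M (-0.10), and its median was -0.24 without liver_395M. The female-biased call was lost without any one of liver_611WT, liver_613WT, liver_464WT, liver_648M, liver_466M and liver_411M (adjusted p = 0.0762 to 0.224). The hepatocyte call was lost without liver_464WT (-0.06), liver_463M (-0.08), liver_395M (-0.08), liver_616WT (-0.10) or liver_611WT (-0.11), and its median was -0.20 without liver_613WT. Pericentral medians were -0.05, -0.07, -0.19 and -0.20 without liver_464WT, liver_411M, liver_466M and liver_616WT, and the fetal liver median was 0.38 without liver_464WT. Between WT ages, xenobiotic metabolism genes had a median of -0.45, with 2 of 25 higher and 9 lower at 14 weeks, and acute phase genes -0.18, with 6 of 20 lower, counts that were the same adjusted over the list alone (adjusted p = 0.114 and 0.286 with an estimated correlation). Fry called both, at 9.26e-04 and 0.0156.

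Among the lists that did not pass camera between Trim24-/- and WT at 5 weeks, medians were 0.02 for cell cycle, 0.18 for fetal liver genes, 0.03 for acute phase genes, -0.05 for endoplasmic reticulum stress, -0.16 for retinoid storage and metabolism and 0.09 for neutrophil markers. In limma no member of these lists was called, adjusted over the list alone 0, 2, 0, 0, 0 and 0 passed, the 2 being higher, and at an unadjusted p under 0.05 there were 0, 2, 4, 0, 5 and 0.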
